A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

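Total RNA was sequenced from 4 libraries of *Saccharomyces cerevisiae*, 2 of the wild-type strain and 2 of a strain lacking CHD1, which encodes a chromatin-remodelling ATPase. Per the labels, both strains were in the BY4741 background, were grown at 30 °C in YPD, a rich glucose medium, and were collected in mid-log phase. RNA was extracted with hot acid phenol, libraries were made with a multiplexing kit intended for small RNA, and sequencing was done on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, TopHat and the genome build sacCer3. The version of TopHat, the program that counted reads, the gene annotation, the use of strand and the treatment of reads with several equally good positions are not given in the sources used here.

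For each library the authors deposited a gene table and an intron table. The deposited gene tables hold whole-number read counts for 5816 genes, with the length of each gene, per the file headers. A second deposited column, labelled as a normalized read number in the file headers, was equal to the read count divided by the feature length and by 1 constant per library, the same constant in the gene table and the intron table. This column entered no test and served only to recover the constant, which in units of 1e6 reads was 13.98 and 15.53 for wild-type replicates 1 and 2 and 25.11 and 17.43 for deletion replicates 1 and 2. The deposited intron tables hold counts for 793 features. Compared with the reference annotation, 253 of these matched an annotated intron exactly, 23 were introns in 5′ untranslated regions and 517 were coding exons of intron-containing genes; the exons were left out of the intron tests. The 253 introns lie in 243 genes, and 91 of them lie in ribosomal protein genes. The gene counts include reads from introns. Of the gene identifiers, 5813 were found in the annotation of the R64 assembly, whose chromosomes are those of sacCer3; coordinates are 1-based on that build.

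Gene reads per library were 2145684 and 2824770 in wild-type replicates 1 and 2, and 4117998 and 2597514 in deletion replicates 1 and 2. At least 10 reads were counted on 5306, 5446, 5581 and 5470 genes in the same order. Introns held far fewer reads: 6608, 10368, 9685 and 5985, of which 3616, 6580, 5018 and 2882 fell in the 8 introns that hold a snoRNA gene. An intron with few reads therefore has a wide standard error, and the intron tests were restricted to those with enough reads. The 6 genes that overlap annotated ribosomal RNA genes took 207399, 218919, 430894 and 300884 reads. TAR1 and YLR154C-G held most of these, and since the use of strand in counting is not given, their reads cannot be told apart from ribosomal RNA.

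Groups were taken from the genotype in the labels. The main test was edgeR's quasi-likelihood test (version 4.0.16, in R 4.3.3) on the deposited counts, with TMM factors, the filterByExpr filter at its minimum count of 10, genotype as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM (counts per 1e6 reads) were computed on the TMM-scaled library sizes; the TMM factors were 0.945 and 0.984 for the wild-type replicates and 1.04 and 1.03 for the deletion replicates. Introns were tested as their own table with the library sizes and factors of the gene table. The change of an intron relative to its gene was the interaction of feature type and genotype over 8 columns per intron, with library as a block. Introns in 5′ untranslated regions were left out of this test and of the intronic share. The intronic share was the sum of intron reads over the sum of reads of the genes holding them, compared by a two-sided exact permutation test, which with 2 samples against 2 cannot give a p below 0.333. Wilson intervals at 95% confidence were computed for shares of single libraries.

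Gene lists covered ribosomal protein genes, ribosome biogenesis, splicing factors, transcription elongation factors, chromatin remodelers with histone chaperones and histone methylation, histones, the induced environmental stress response, heat-shock chaperones, the PHO regulon, Gcn4 targets of amino acid biosynthesis, sulfur metabolism, glycolysis, respiration, hexose transport, the iron regulon, ergosterol synthesis, mating and a-cell genes, alpha-cell genes, daughter-cell genes, G1/S genes and meiosis genes. They were written from general knowledge of yeast and tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over the 21 lists. Camera with an estimated correlation and fry were run beside it. The p of fry asks whether the genes of a list moved, on balance, one way, and does not compare the list with other genes. Genes deleted from the strain background were examined apart. ARG5,6 was not matched to the gene tables. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined.

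By that rule the text names CHD1; the 12 genes with the largest rise and the 12 with the largest fall past the threshold, with a mean of at least 20 reads in the higher group and no overlap between the groups; up to 3 members of each list past the threshold, or else the 2 with the smallest p; the introns with the largest changes past the threshold; and the genes of the 10 introns with most reads. Any other gene was named after its values were seen.

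The tests were tried on simulated data. Counts were drawn for 5476 genes at the real means and library sizes with known changes in some of them. edgeR recovered 43 of 67 genes changed by 1.5-fold, 60 of 67 changed by 2-fold and 65 of 66 changed by 4-fold, and 6 of its 174 calls were unchanged genes. With no gene changed, it called 0 of 5465 genes, while 5.07% had an unadjusted p under 0.05. Over 20 draws of the 21 lists, camera with the preset correlation called 0 lists with no change. It called the PHO list of 21 genes in all 20 draws in which it was lowered to its observed median. Genes were drawn independently of each other, so these draws cannot say how often camera calls lists of correlated genes that did not change. For introns, over 10 draws of each size, 91 of 176 introns changed by 2-fold and 170 of 178 changed by 4-fold were recovered. Relative to the gene the numbers were 79 of 151 and 149 of 157. Unchanged introns made up 5 of 96 calls in the 2-fold draws and 4 of 174 in the 4-fold draws. Relative to the gene they made up 4 of 83 and 12 of 161.

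The alternatives tried were DESeq2 1.42.0, limma-voom, RLE factors, total gene counts as library sizes, no filter, a filter of 50 reads in each of 2 libraries, an adjusted p under 0.1, the replicate number as a block, leaving out each library in turn, ribosomal protein genes left out of the normalization, TMM factors from the introns, and other forms of the intronic share. Pseudocounts and filters planned for normalized values were not run, because counts were deposited. After the data were seen, further alternatives were added: intron reads taken out of the gene counts, genes on ribosomal RNA left out, introns with a snoRNA left out, the intron of IMD4 left out of the intronic share, exon counts in place of gene counts, each library left out for further sets of introns, and lists of intron-containing genes and of genes near chromosome ends. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.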

Results

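RNA levels of wild-type budding yeast were compared with those of a strain lacking CHD1, with 2 libraries of each genotype from cells in mid-log growth in rich medium. Reads had been counted over genes and, separately, over the introns of intron-containing genes. The libraries held 2145684 and 2824770 gene reads in wild-type replicates 1 and 2, and 4117998 and 2597514 in deletion replicates 1 and 2. Pearson correlations of log2 CPM across genes were 0.986 between the wild-type libraries and 0.991 between the deletion libraries, and lay between 0.979 and 0.983 across genotypes; genes are not independent replicates. Counts of replicate libraries differed beyond sampling noise, with a chi-square per degree of freedom of 6.26 in wild type and 2.49 in the deletion. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Unless another test is named, adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, errors of log2 fold changes are standard errors, and levels are mean CPM ± SD with n = 2.

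CHD1 itself (YER164W, chromosome V, 505392 to 509798) was counted 211 and 396 times in the wild-type libraries and 7 and 3 times in the deletion libraries, or 104 and 143 CPM against 1.63 and 1.12 CPM. The log2 fold change was -6.40 ± 0.27 (adjusted p = 3.34e-11), and the low counts lay in the libraries labelled as the deletion. The neighbouring genes did not pass the test: YER163C had a log2 fold change of 0.20 (adjusted p = 0.600) and PAB1, which encodes the poly(A)-binding protein, one of -0.27 (adjusted p = 0.104). Other markers of the strain background gave a mixed picture. MET17, deleted in BY4741, had 0 reads in every library, and LEU2 had 0 and 2 reads in wild type and 0 and 2 in the deletion. URA3, also deleted in that background, was nonetheless counted 29, 43, 82 and 52 times, which the labels leave unexplained. HIS3 was counted 69, 99, 104 and 79 times. The labels do not say how much of HIS3 the background lacks, so its reads do not speak against the labelled strain. STE2, the a-cell pheromone receptor, had 1083, 1324, 2588 and 1567 reads, while the alpha-factor gene MF(ALPHA)1 had 0, 0, 1 and 0.

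The comparison of the 2 genotypes asked which transcripts depend on CHD1, a chromatin remodeller that the series title links to elongation factors and to histone methylation over transcribed and spliced genes. In the cells without CHD1, 13 of 21 genes for phosphate acquisition and polyphosphate storage fell, and 10 of 51 genes of the stress response rose. PHO89, PHO11, PHO12 and PHO84 fell by 1.93 or more on the log2 scale, and HSP12, CAT2 and HSP26 rose by 1.67 or more. Of 5488 genes tested, 92 were higher and 168 lower in the deletion (4.74% changed), and 40 of these changed by at least 2-fold, 24 upward and 16 downward. The median log2 fold change of all genes was 0.004. Scaling by total gene counts instead of TMM shifted that median to 0.11 and turned the split to 176 higher and 65 lower. The number of changed genes was 577 without wild-type replicate 1, 133 without deletion replicate 1 and 148 without deletion replicate 2. DESeq2 called 153, of which 33 were higher. In the fits without 1 library the spread came from the other genotype's pair alone. Their numbers of calls therefore also depend on that pair.

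**Figure D1:**
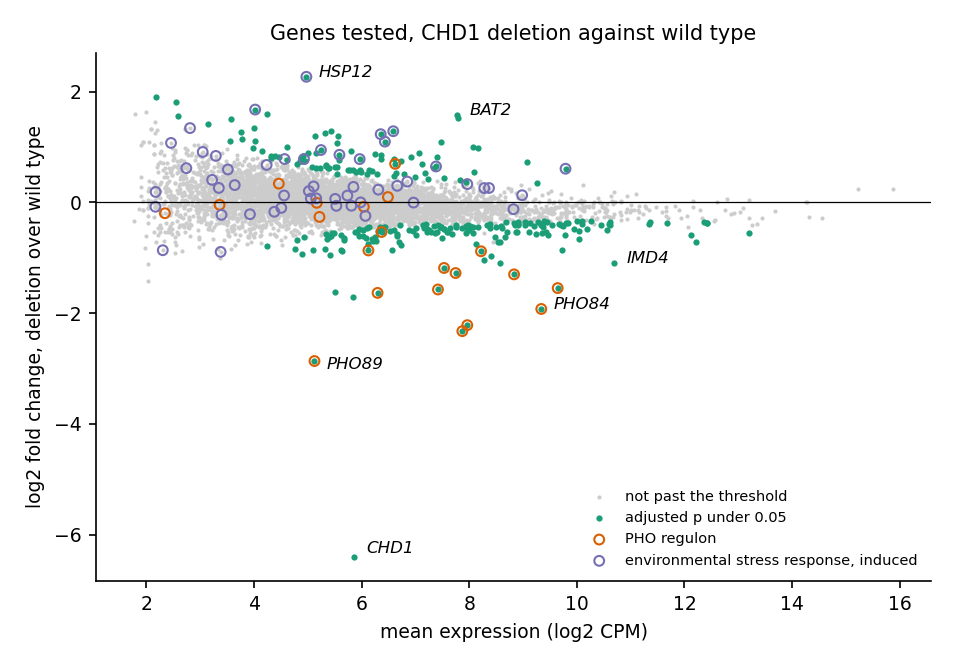
Log2 fold change (deletion over wild type, TMM-scaled) against mean expression in log2 CPM for the 5488 genes tested, 1 point per gene; filled coloured points passed the adjusted p threshold of 0.05, and open circles are the tested members of the PHO and stress lists. CHD1 lies at -6.40, PHO89 at -2.87 and HSP12 at 2.27.

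Among the genes with the largest rises, HSP12 (YFL014W, chromosome VI, 107256 to 107585), which encodes a small stress-induced membrane protein, went from 9.59 ± 1.70 to 46.8 ± 3.28 CPM (log2 fold change 2.27 ± 0.20, adjusted p = 6.93e-07). BNA4, which encodes an enzyme of NAD synthesis from tryptophan (chromosome II, 39145 to 40527), went from 112 ± 14.8 to 320.5 ± 15.1 CPM (1.52 ± 0.12, adjusted p = 8.24e-08). BAT2, which encodes the cytosolic branched-chain amino acid aminotransferase (chromosome X, 705744 to 706874), went from 108 ± 29.2 to 320.0 ± 42.1 CPM (1.58 ± 0.15, adjusted p = 1.0e-06). The small chaperone gene HSP26 rose by 1.67, RGI1, induced in respiratory growth, by 1.59, and the glycogen phosphorylase gene GPH1 by 1.28. DCG1 rose by 1.51, GPG1 by 1.35 and RTC3 by 1.29. CAT2, which encodes carnitine acetyltransferase (1.82, adjusted p = 0.0150), the cell-wall iron-siderophore gene FIT2 (1.55, adjusted p = 0.0481) and YGL081W (1.42, adjusted p = 0.0171) rose from low counts, for YGL081W from 6 and 14 wild-type reads. Without deletion replicate 1 the adjusted p of these 3 genes rose above the threshold, as did those of CAT2 and FIT2 without wild-type replicate 2.

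After CHD1 itself, phosphate genes made up 10 of the 12 largest falls. PHO84, which encodes the high-affinity phosphate transporter (YML123C, chromosome XIII, 24037 to 25800), went from 1036 ± 45.4 to 272 ± 12.2 CPM (log2 fold change -1.93 ± 0.10, adjusted p = 3.96e-10). PHO89, the sodium-coupled phosphate transporter gene (YBR296C, chromosome II, 796798 to 798522), went from 66.9 ± 8.05 to 9.24 ± 1.21 CPM (-2.87 ± 0.19, adjusted p = 1.07e-08), a 7.29-fold decrease. VTC3, which encodes a subunit of the vacuolar polyphosphate polymerase (chromosome XVI, 514511 to 517018), went from 1200.1 ± 47.5 to 410.0 ± 10.1 CPM (-1.55 ± 0.10, adjusted p = 4.74e-09). The acid phosphatase genes PHO11 (-2.33), PHO12 (-2.22) and PHO5 (-1.57) fell, as did the alkaline phosphatase gene PHO8 (-1.28), SPL2 (-1.64), which restrains low-affinity phosphate uptake, VTC4 (-1.30) and VTC1 (-1.19). PHO11 and PHO12 are near-identical, so how their reads divide between them is uncertain. The other 2 of the 12 were YLR460C (-1.72) and YCR102C (-1.62), related oxidoreductase-family genes whose reads may be shared. In the PHO list of 21 tested genes, 13 fell, 1 rose and 7 did not pass, and the counts adjusted over the list alone were again 13 and 1. The number lower was 12 with total gene counts and without either deletion replicate, and 11 with DESeq2; in each of these PHO86 was among those lost. The 3 further members that fell, named after their values were seen, were VTC2 (-0.88), the kinase inhibitor gene PHO81 (-0.87) and PHO86 (-0.54); HOR2, which encodes a glycerol-3-phosphatase, rose by 0.69. The list had a median of -0.88 and a camera adjusted p of 6.73e-12 (adjusted p = 0.321 with an estimated correlation). The fry test, which asks only whether its genes moved one way, gave an adjusted p of 0.00395.

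**Figure D2:**
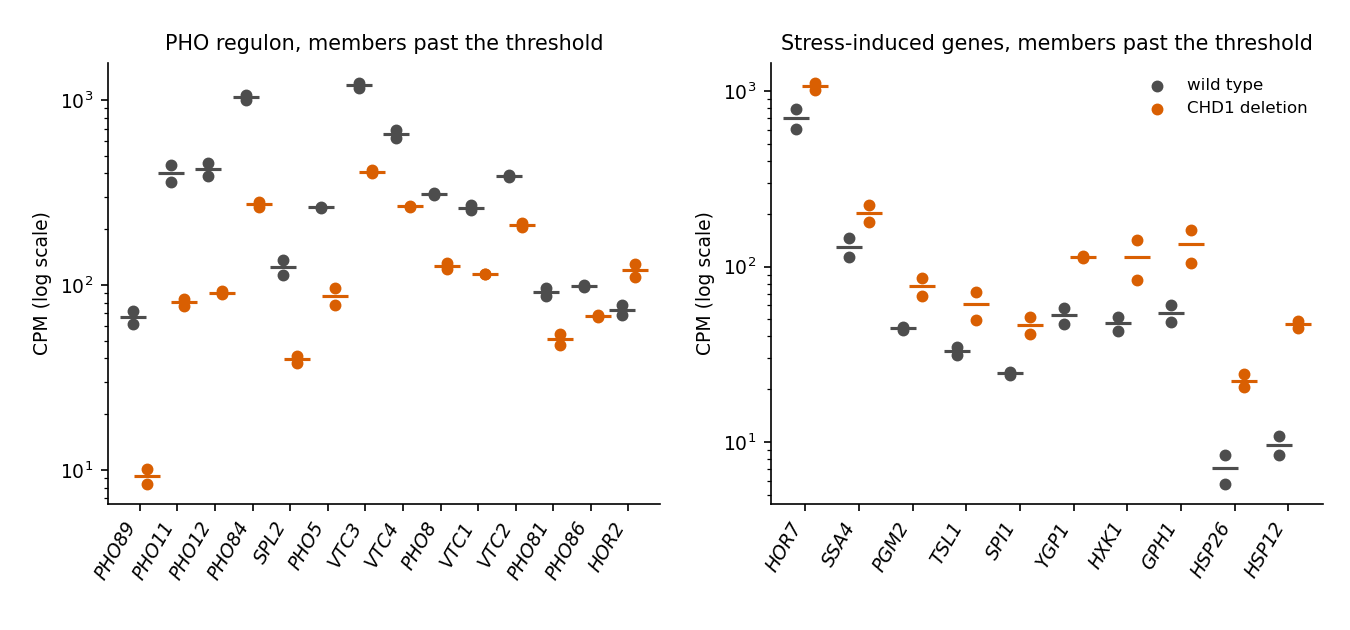
TMM-scaled CPM on a log axis of the members of the PHO list (left) and of the stress-induced list (right) that passed the threshold, 1 point per library, with a bar at the mean of the 2 libraries of each genotype. Deletion libraries lie below wild type for 13 PHO genes and above it for HOR2 and for the 10 stress genes.

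Of 51 tested genes induced in the environmental stress response, 10 rose, 0 fell and 41 did not pass; adjusted over the list alone, 19 were higher and 1 lower. At an unadjusted p under 0.05 there were 22 members, and DESeq2 called 7 higher and 0 lower. DESeq2 gave no adjusted p for HSP12, HSP26 and SPI1, which were among the 10. Besides HSP12, HSP26 and GPH1, the 10 were the hexokinase gene HXK1 (1.23), the secreted glycoprotein gene YGP1 (1.10), the cell-wall gene SPI1 (0.94), TSL1 of trehalose synthesis (0.86), the phosphoglucomutase gene PGM2 (0.78), the Hsp70 gene SSA4 (0.65) and HOR7 (0.61), these 7 named after their values were seen. SPI1 lost its call without deletion replicate 1, and TSL1 and SSA4 without deletion replicate 2. The list had a median log2 fold change of 0.28 and a camera adjusted p of 1.89e-06 (adjusted p = 0.511 with an estimated correlation). The median was 0.12 without deletion replicate 2 and 0.46 without deletion replicate 1, and 16 members were higher without wild-type replicate 1.

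Of 137 tested ribosomal protein genes, 12 fell, 0 rose and 125 did not pass, with 16 lower and 0 higher adjusted over the list alone; 39 members had an unadjusted p under 0.05, and DESeq2 called 12 lower and 0 higher. The largest falls were those of RPS22B (-0.54 ± 0.10, adjusted p = 0.00217), RPS14B (-0.54 ± 0.11, adjusted p = 0.00627) and RPL22B (-0.49 ± 0.11, adjusted p = 0.0167), and each has a paralog with which reads can be shared. The list median was -0.13, with a camera adjusted p of 1.89e-06 (adjusted p = 0.511 with an estimated correlation), and it was -0.03 with total gene counts and -0.08 without wild-type replicate 1. Members called lower numbered 3 with total gene counts, 0 without deletion replicate 1, 3 without deletion replicate 2, 21 without wild-type replicate 1 and 34 without wild-type replicate 2. Of 89 tested ribosome biogenesis genes, 2 fell, UTP21 (-0.44) and the RNA helicase gene DBP2 (-0.38), and 87 did not pass, with 0 in either direction adjusted over the list alone. Their median was -0.03, and 0.08 with total gene counts (camera adjusted p = 0.305). Without deletion replicate 1, camera with the preset correlation called the ribosome biogenesis list lower (median -0.10). With all 4 libraries and an estimated correlation, 0.27, its camera adjusted p was 0.870. The calls of UTP21 and DBP2 were lost with total gene counts and without deletion replicate 2. UTP21 also lost its call with DESeq2 and without wild-type replicate 2, and DBP2 with the stricter filter and without deletion replicate 1.

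Of 59 tested amino acid biosynthesis genes that Gcn4 activates, 11 fell, 2 rose and 46 did not pass; adjusted over the list alone, 17 were lower and 4 higher. GDH1, the glutamate dehydrogenase gene that assimilates ammonium, had the largest fall (-1.10 ± 0.11, adjusted p = 2.49e-06), from 524 ± 49.6 to 245 ± 24.6 CPM, and ARG1 of arginine synthesis fell by 0.86. Named after their values were seen, the branched-chain genes LEU1 (-0.85), BAT1 (-0.71) and ILV5 (-0.66) and the lysine gene LYS9 (-0.76) fell, while BAT2, the cytosolic counterpart of BAT1, was among the 2 that rose, the other being the serine synthesis gene SER3 (0.69). The list median was -0.15 (camera adjusted p = 0.00125; adjusted p = 0.353 with an estimated correlation; fry adjusted p = 0.00707). It was -0.04 with total gene counts and -0.09 without deletion replicate 2, where 7 members were lower.

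In central carbon metabolism, 4 hexose transporter genes rose and 3 glycolytic genes fell. HXT6 (0.99 ± 0.12, adjusted p = 3.91e-05) and HXT7 (0.99 ± 0.12, adjusted p = 3.43e-05), high-affinity transporter genes so alike that their reads cannot be divided with certainty, rose with HXT4 (0.90) and, named after its values were seen, HXT1 (0.85), whose call was lost without deletion replicate 1. These were the 4 higher members of 25 hexose transport and galactose genes, of which 0 were lower and 21 did not pass. Adjusted over the list alone 5 were higher and 2 lower (10 members had an unadjusted p under 0.05, DESeq2 called 4 higher and 0 lower, median 0.10, camera adjusted p = 0.354). Of 24 glycolysis and fermentation genes, 3 fell and 21 did not pass: the alcohol dehydrogenase gene ADH4 (-0.50), the phosphofructokinase gene PFK2 (-0.35) and TDH2 (-0.35), one of the alike glyceraldehyde-3-phosphate dehydrogenase genes. Adjusted over the list alone 5 were lower, and the camera adjusted p was 0.00340 at a median of -0.17 (adjusted p = 0.353 with an estimated correlation). Of 53 respiration and TCA cycle genes, 3 rose, 3 fell and 47 did not pass, and the same counts were found adjusted over the list alone (median 0.10, camera adjusted p = 0.221). COX5B (0.89), the hypoxic isoform of a cytochrome oxidase subunit, QCR8 (0.62) and, named after its values were seen, LSC2 (0.51) rose. The peroxisomal citrate synthase gene CIT2 (-0.94) and, likewise named later, NDE1 (-0.53) and MDH2 (-0.40) fell. Over this list DESeq2 called 0 higher and 1 lower, and it gave no adjusted p for COX5B, QCR8 and CIT2. The 3 glycolytic calls were lost with total gene counts and without either deletion replicate, those of ADH4 and PFK2 also without wild-type replicate 2. ADH4 also lost its call with DESeq2, and PFK2 and TDH2 with the stricter filter. Without wild-type replicate 1 the glycolysis list did not pass camera, at a median of -0.11. COX5B lost its call without deletion replicate 2, and QCR8 without either deletion replicate or wild-type replicate 2; without deletion replicate 2, 0 respiration genes were higher and 1 lower. LSC2 lost its call with DESeq2 and in each fit without 1 library except that without wild-type replicate 1, as did MDH2, which also lost it with total gene counts and the stricter filter; NDE1 lost it with total gene counts and without deletion replicate 2.

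Among the remaining nutrient lists, 4 iron genes fell and 1 rose. FET4, a low-affinity iron transporter gene (-0.77), the siderophore transporter genes SIT1 (-0.75) and ENB1 (-0.72) and the mitochondrial iron carrier gene MRS4 (-0.66) fell and FIT2 rose, among 30 tested with 25 not past the test; ENB1 and MRS4 were named after their values were seen. MRS4 lost its call with DESeq2, with total gene counts, without wild-type replicate 1 and without deletion replicate 1, and FIT2 with limma-voom, without wild-type replicate 2 and without deletion replicate 1. Adjusted over the list alone, 2 iron genes were higher and 4 lower (median -0.13, camera adjusted p = 0.332). Of 27 ergosterol synthesis genes, 3 fell, MVD1 (-0.52), ERG10 (-0.40) and ERG11 (-0.40), and 24 did not pass, with the same 3 in number adjusted over the list alone (median -0.12, camera adjusted p = 0.0154; adjusted p = 0.495 with an estimated correlation). The calls of these 3 genes were lost with total gene counts and without deletion replicate 1. MVD1 also lost its call with DESeq2 and without wild-type replicate 2, and ERG10 and ERG11 without deletion replicate 2. The camera adjusted p of the ergosterol list was 0.242 without wild-type replicate 1 and 0.0582 without deletion replicate 1. Of 32 sulfur and methionine genes, 3 fell and 29 did not pass: the glutathione synthesis gene GSH1 (-0.86) and the cysteine synthesis genes CYS3 (-0.54) and CYS4 (-0.42). Adjusted over the list alone 4 sulfur genes were lower and 1 higher; the list's median was -0.0009, its mean 0.05 and its camera direction down while that of fry was up (camera adjusted p = 0.927), and the median was 0.10 with total gene counts. CYS3 and CYS4 lost their calls with total gene counts and without deletion replicate 1, CYS3 also without wild-type replicate 2 and CYS4 also without deletion replicate 2.

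The lists closest to the role of CHD1 did not pass as lists, and 1 of their genes changed. Of 72 splicing factor genes, 0 passed the test in either direction, with 7 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.305). The smallest p-values were those of PRP31 (0.77 ± 0.22, adjusted p = 0.0544) and MUD1 (0.63 ± 0.19, adjusted p = 0.0681). With total gene counts 3 splicing genes were called higher, with RLE factors 1, and with ribosomal protein genes left out of the normalization 1. Of 24 elongation factor genes, 0 passed, with 5 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 adjusted over the list alone. Their median was -0.03, their mean -0.0002, and the median was 0.07 with total gene counts (camera adjusted p = 0.834). ELP3, an Elongator subunit gene, had a value of -0.28 (adjusted p = 0.144) and LEO1, of the Paf1 complex, one of 0.31 (adjusted p = 0.163). Of 50 genes of other chromatin remodelers, histone chaperones and histone methylation enzymes, JHD2, which encodes the H3K4 demethylase, rose (0.61 ± 0.16, adjusted p = 0.0326) and 49 did not pass. Of the 50, 0 were past the threshold adjusted over the list alone (median 0.04, camera adjusted p = 0.545). DESeq2 gave no adjusted p for JHD2, and its call was lost without either deletion replicate. Of 11 histone genes, 0 passed, 1 was higher adjusted over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 0 (median 0.10, camera adjusted p = 0.170). HHF2, of histone H4, had a value of 0.31 (adjusted p = 0.0582) and HHT1, of histone H3, one of 0.21 (adjusted p = 0.234).

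Of 23 tested chaperone genes of the heat shock response, the Hsp40 gene SIS1 (-0.60) and the coactivator gene MBF1 (-0.72) fell and 21 did not pass, with 5 lower and 1 higher adjusted over the list alone (median -0.14, camera adjusted p = 0.0154; adjusted p = 0.388 with an estimated correlation; fry adjusted p = 0.00395). The camera adjusted p was 0.0507 without wild-type replicate 1. Of 35 G1/S genes, POL30 of the replication clamp (-0.54) and the thymidylate synthase gene CDC21 (-0.95) fell and 33 did not pass, with 8 lower and 0 higher adjusted over the list alone (median -0.18, camera adjusted p = 0.00202; adjusted p = 0.353 with an estimated correlation). CDC21 had 54.7 ± 32.6 CPM in wild type and 29.8 ± 3.30 in the deletion, and its groups overlapped. Its log2 fold change ran from -1.40 to -0.10 over the alternatives. Its call was lost under several of them, among them without wild-type replicate 2, and that of POL30 without deletion replicate 1. Of 31 mating and a-cell genes, MFA2 of a-factor rose (0.48), PRM7 fell (-0.63) and 29 did not pass, with 2 higher and 3 lower adjusted over the list alone (median 0.04, camera adjusted p = 0.437). MFA2 lost its call with DESeq2, with limma-voom and without deletion replicate 1. PRM7 lost its call with total gene counts, without either deletion replicate and without wild-type replicate 2. Of 18 daughter-cell genes, DSE1 rose (0.55) and 17 did not pass, with 1 higher adjusted over the list alone; the median was -0.06, and 0.05 with total gene counts (camera adjusted p = 0.809), and DSE1 lost its call without deletion replicate 2. Of the 4 alpha-cell genes with enough reads, 0 passed the test over all genes, 1 was higher adjusted over the list alone, 1 had an unadjusted p under 0.05 and DESeq2 called 0 (median 0.25, camera adjusted p = 0.0520). With the preset correlation, camera called the alpha-cell list higher with RLE factors and with intron reads taken out of the genes. It did so too without wild-type replicate 1 and without deletion replicate 2. The list's median lay between 0.08 and 0.40 when 1 library was left out. With an estimated correlation, 0.41, its camera adjusted p was 0.511. MATALPHA1 (1.04, adjusted p = 0.0642) shares its sequence with the silent HML locus, so its reads and those of HMLALPHA2 (0.25, adjusted p = 0.561) cannot be placed. Of 39 meiosis genes, 0 passed, with 8 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.0901; adjusted p = 0.0346 with intron reads taken out of the genes). DMC1 had a value of -1.41 (adjusted p = 0.0642) and SPO22 one of -0.59 (adjusted p = 0.0760).

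**Figure D3:**
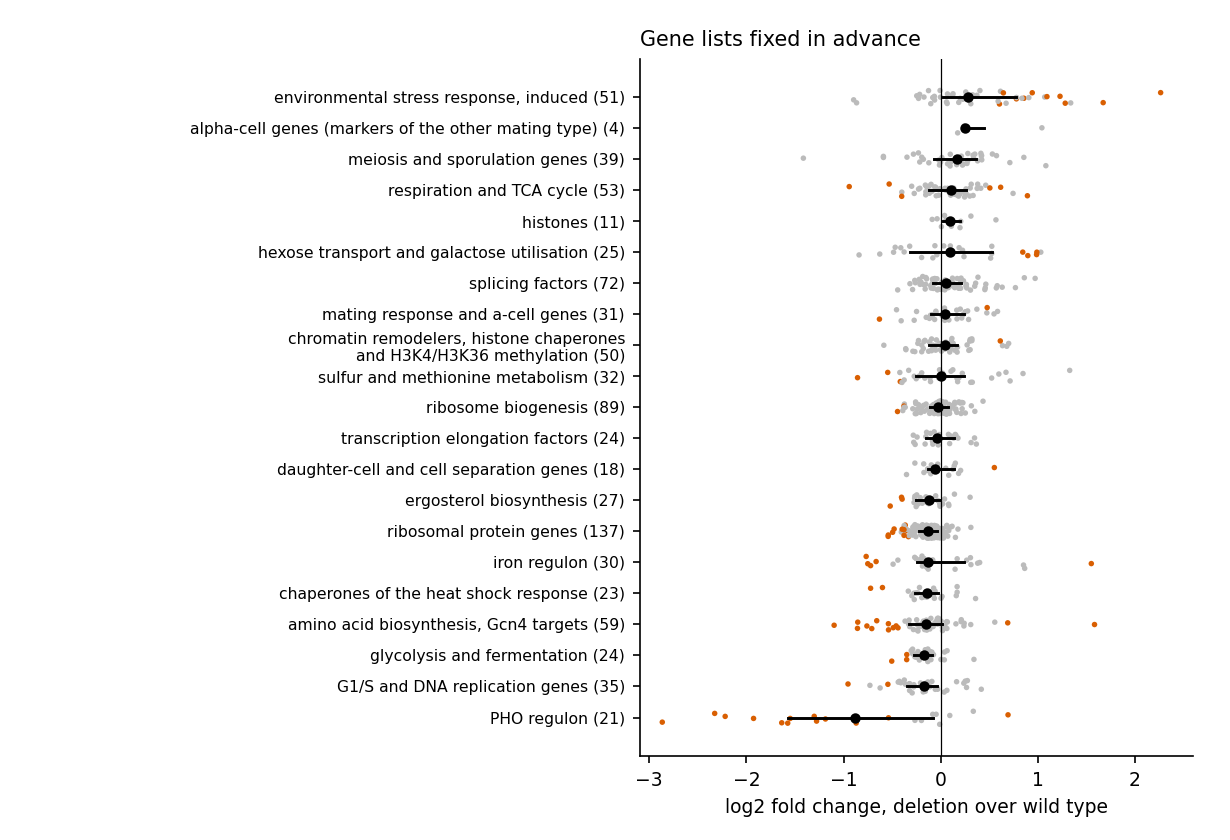
Log2 fold change (deletion over wild type, TMM-scaled) of the tested members of the 21 lists, 1 point per gene, with the number tested in parentheses, orange points past the threshold, a black dot at the median and a black line over the middle quartiles. The PHO list has a median of -0.88 and the stress-induced list one of 0.28; with total gene counts the medians of the ribosome biogenesis, elongation, sulfur and daughter-cell lists change sign, as the median of all genes moves to 0.11.

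In all, camera called 8 of the 21 lists with the preset correlation, 0 with the correlation estimated from these 4 libraries, and fry called 3.

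Because CHD1 has been linked to spliced genes, the reads inside introns were compared next. Of 90 introns with enough reads, 72 of them in ribosomal protein genes, 8 were lower in the deletion past the threshold and 0 were higher. A negative log2 fold change was found in 71 of the 90. The intron of IMD4, a gene for an IMP dehydrogenase of guanine nucleotide synthesis (chromosome XIII, 163309 to 163716), went from 1517 ± 470.1 to 624 ± 50.7 CPM (-1.28 ± 0.28, adjusted p = 0.00047). It holds the snoRNA gene SNR54 and was counted 2399, 5138, 2835 and 1574 times. The intron of RPL20B (chromosome XV, 900768 to 901193) went from 14.8 ± 0.0387 to 5.62 ± 1.04 CPM (-1.43 ± 0.31, adjusted p = 0.00047), from 30 and 41 reads to 21 and 17. Introns of RPL35B (-1.68), RPS30A (-1.27), RPS10B (-1.20) and VMA10 (-1.08), a gene for a subunit of the vacuolar ATPase, also fell, as did, named after their values were seen, those of RPL42B (-1.02) and the 5′ untranslated region of RPS22B (-0.93). Among introns with a positive value, the smallest p-values were those of DBP2 (0.99, adjusted p = 0.292), RPL22A (0.47, adjusted p = 0.292) and BUD25 (0.55, adjusted p = 0.371). The median was -0.37 over all introns, -0.41 in ribosomal protein genes and -0.25 in other genes; fry over all introns gave p = 0.00383, and camera of ribosomal protein against other introns p = 0.153 (p = 0.269 with an estimated correlation). In all, 15 introns had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 8. TMM factors from the introns themselves left 2 lower and 2 higher and a median of -0.04, and between 0 and 4 introns were called when any 1 library was left out; in these 4 fits the call of IMD4 held only without wild-type replicate 1.

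The genes holding the 10 introns with most reads were examined for their own change. IMD4 fell (-1.09 ± 0.12, adjusted p = 7.49e-06), from 2261 ± 431 to 1060 ± 91.9 CPM, reads that include its intron and can be shared with the alike IMD3. HAC1, the transcription factor gene of the unfolded protein response, fell (-0.42, adjusted p = 0.0143); its intron is removed outside the spliceosome. RPS22B (-0.54), RPL7A (-0.36, adjusted p = 0.0327) and RPS13 (-0.33, adjusted p = 0.0433) fell too. RPL28 (-0.18, adjusted p = 0.312), ASC1 (-0.29, adjusted p = 0.152) and EFB1 (-0.17, adjusted p = 0.336) did not pass, nor did RPL30 (-0.04, adjusted p = 0.880) and RPS9A (-0.02, adjusted p = 0.948), whose values were 0.07 and 0.09 with total gene counts. The calls of HAC1, RPL7A and RPS13 were lost with total gene counts and without either deletion replicate, that of RPS13 also with the stricter filter.

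Relative to the gene that holds it, the intron of RPL20B fell and no other intron passed the test. Of 80 introns with enough reads, those in 5′ untranslated regions left out, RPL20B was the 1 lower (-1.29 ± 0.30, adjusted p = 0.00259), and 0 were higher. The 5′ untranslated intron of RPS22B therefore had no such test. Among those with a positive value, the introns of RPL22A (0.76), DBP2 (1.33) and EFB1 (0.44) had the smallest p-values, each with an adjusted p of 0.136. The median over introns was -0.17, with -0.24 in ribosomal protein genes and -0.03 in other genes (fry over all introns p = 0.0399; camera of ribosomal protein against other introns p = 0.0223; p = 0.132 with an estimated correlation). At an unadjusted p under 0.05 there were 13 introns, and DESeq2 and limma-voom called 0. The call of RPL20B was lost with the replicate number as a block and when any 1 library other than wild-type replicate 1 was left out; without that replicate 6 introns were called.

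**Figure D4:**
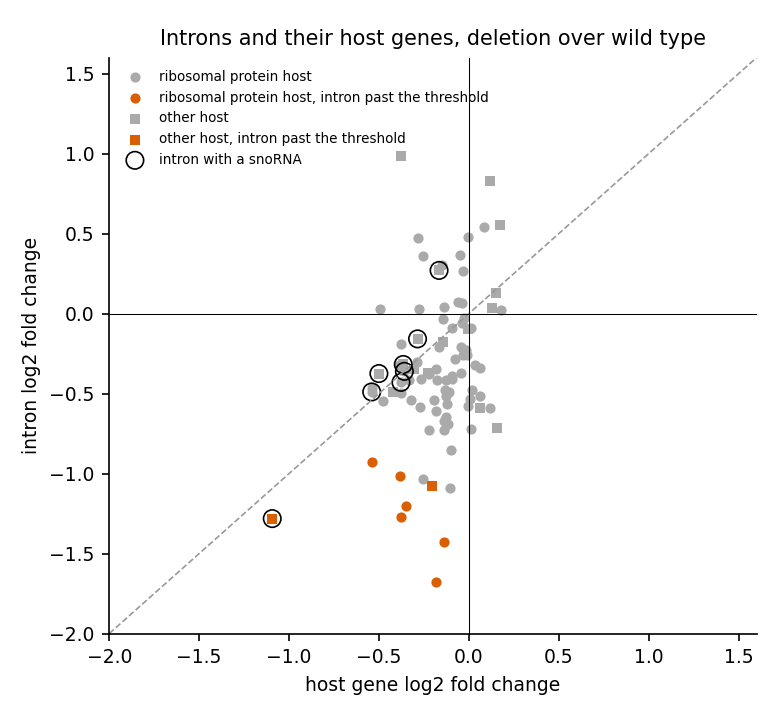
Log2 fold change (deletion over wild type, gene-table TMM factors) of 90 introns on the y axis against that of their host genes on the x axis, 1 point per intron, orange where the intron passed the threshold and ringed where it holds a snoRNA gene; the dashed line marks equal change. The introns of RPL20B (-1.43) and RPL35B (-1.68) lie farthest below the line among those past the threshold; that of IMD4 (-1.28) lies near the line, but 58.7% to 72.1% of the reads of its gene are those of the intron, without which the gene had a log2 fold change of -0.77.

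The intronic share of reads was lower in both deletion libraries, and most of that fall came from IMD4. The gene itself fell (-1.09), and the intron was 60.5% and 72.1% of its reads in wild type and 58.7% and 59.1% in the deletion. Relative to the gene, whose reads include it, the intron had a log2 fold change of -0.17 ± 0.15 (adjusted p = 0.651). The fall in the share thus partly reflects fewer reads of an intron-rich gene. Introns held 2.12% (95% Wilson interval 2.07 to 2.17) and 2.42% (2.37 to 2.46) of the reads of their genes in wild type, and 1.68% (1.65 to 1.72) and 1.66% (1.62 to 1.70) in the deletion; intervals cover counting error only. The means were 2.27% ± 0.213 and 1.67% ± 0.0163 (SD, n = 2), a log2 ratio of -0.44, with the smallest exact two-sided permutation p that the design allows, 0.333. Without the intron of IMD4 and its gene the shares were 1.37% and 1.24% in wild type and 1.20% and 1.23% in the deletion, a log2 ratio of -0.10 (-0.17 to -0.03 when 1 library was left out). In ribosomal protein genes the share was 1.08% ± 0.101 against 0.946% ± 0.0109 (-0.20), and in other genes 7.31% ± 1.87 against 4.87% ± 0.0606 (-0.59), each with an exact p of 0.333. When 1 library was left out, the log2 ratio lay between -0.29 and -0.10 in ribosomal protein genes and between -0.82 and -0.30 in other genes, the latter without wild-type replicate 2. Without IMD4 the share of other genes was 2.31% ± 0.0555 against 2.46% ± 0.102 and thus higher in the deletion (0.09). In other genes without the introns that hold a snoRNA the log2 ratio was -0.12 (-0.19 to -0.06 when 1 library was left out). Much of this set is 1 gene, HAC1, which itself fell (-0.42). Its intron held 313 of 606 and 406 of 835 intron reads in wild-type replicates 1 and 2. In deletion replicates 1 and 2 it held 443 of 1056 and 298 of 712. The set was not tried without HAC1, so this value cannot be read as a fall across introns. In each library the median over introns of the log2 ratio to the gene was also taken. Between genotypes these library medians differed by -0.17 over 80 introns (exact p = 0.333), but by -0.0391 in ribosomal protein genes (exact p = 0.667) and 0.0346 in other genes (exact p = 1). Such a difference is not the median of the changes of single introns relative to the gene, which was -0.17, -0.24 and -0.03 in the same order. The 8 introns that hold a snoRNA carried 10.7% ± 2.77 of their genes' reads in wild type and 7.53% ± 0.255 in the deletion, and the 245 others 1.03% ± 0.0687 and 0.923% ± 0.0364, log2 ratios of -0.51 and -0.16 (exact p = 0.333 in both). When 1 library was left out, the log2 ratio of the snoRNA introns lay between -0.75 and -0.22, the latter without wild-type replicate 2, and that of the others between -0.23 and -0.09; without IMD4 the 7 remaining snoRNA introns carried 3.24% ± 0.0275 in wild type and 3.60% ± 0.0317 in the deletion, a log2 ratio of 0.15. Leaving out IMD4, or libraries from these sets of introns, was chosen after the data were seen.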

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

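The rules for a sample far from its group, for groups with unlike effects and for a signal outside the main measurement were not applied. Each group holds 2 libraries, and there is 1 contrast. The tests below on paralogs, scaling, cultures, growth rate, snoRNA reads, host transcripts and background were chosen only after the result was seen; the test leaving out 1 library was not.

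In the deletion, 13 of the 21 tested members of the PHO list were lower. Reads shared among near-identical phosphatase genes cannot be the whole of it, because 10 of the 18 members other than PHO5, PHO11 and PHO12 were lower past the threshold. Scaling cannot be either, because 12 members were lower with total gene counts. The list's median differed by at most 0.0378 between the libraries of one genotype, against -0.88 between genotypes, but cultures are confounded with genotype, so cultures that differed in phosphate or growth cannot be told apart from the deletion. A direct effect of the missing remodeller on these genes may remain among the open explanations and was not tested.

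In the deletion, 10 of 51 stress response genes were higher and 12 of 137 ribosomal protein genes lower. The median of the stress list was 0.12 without deletion replicate 2 (0.12 to 0.46 over the 4 fits that each leave out 1 library), so that library may carry much of its size, although the list stayed past the camera threshold without it (adjusted p = 0.00552; with all 4 libraries and an estimated correlation it did not pass, adjusted p = 0.511). Slower growth or a denser culture of the deletion strain would lower ribosome biogenesis genes at least as far as ribosomal protein genes, yet the median of the former lay 0.10 above that of the latter (95% bootstrap interval over genes 0.06 to 0.16). The same gap per library was -0.11 and -0.005 in wild type and 0.12 and -0.01 in the deletion, which overlap. Without deletion replicate 1, camera with the preset correlation called ribosome biogenesis genes lower (median -0.10). With all 4 libraries and an estimated correlation they did not pass (camera adjusted p = 0.870). Slower growth therefore cannot be told apart from the deletion. An effect of the deletion itself stays open and untested.

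In the deletion, 71 of 90 tested introns had a negative log2 fold change. Reads of snoRNAs in introns cannot account for all of it, since the 82 tested introns without one had a median of -0.38. Its 95% bootstrap interval, -0.48 to -0.30, is over introns and does not cover variation between libraries. The median of all 90 introns was -0.27 with total gene counts and -0.04 with TMM factors from the introns. Such factors remove a change common to all introns. Summed reads on 57 meiosis genes had a log2 ratio of 0.0705. They were 558 and 556 CPM in the deletion against 531 and 530 in wild type. Of these genes 39 had enough reads to be tested, so their sum need not measure background. Less background in introns therefore cannot be excluded. For IMD4, snoRNA reads counted in the gene are not the whole of its fall either: without the intron's reads it had a log2 fold change of -0.77 ± 0.10 (adjusted p = 8.32e-05). Fewer transcripts of the host genes cannot be told apart from a change within introns. The median relative to the host gene, -0.17 over 80 introns (interval over introns -0.28 to -0.06), lay between the values that each would give. A change in splicing or in transcription through introns may remain open, and neither was tested.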

How the results depend on the processing

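Tests with intron reads taken out of genes, ribosomal RNA genes left out, snoRNA introns or that of IMD4 left out, or exon counts in place of gene counts were chosen only after the results were seen. When a library was left out, the lone sample was assumed to vary like the other group. The spread then came from the remaining pair alone. Its chi-square per degree of freedom was 6.26 in wild type and 2.49 in the deletion. A call lost or gained in such a fit may reflect that spread. It need not mean that the library left out carried the effect. Of the 61 genes past the threshold that were named by the rule, 61 kept their call with RLE factors, with no filter, with the replicate number as a block, with ribosomal protein genes left out of the normalization, without wild-type replicate 1, with intron reads taken out and with ribosomal RNA genes left out. The number kept was 58 with limma-voom, 45 with total gene counts, 52 of 57 tested with the stricter filter, 51 without wild-type replicate 2, 38 without deletion replicate 1, 45 without deletion replicate 2, and 42 with DESeq2, which gave no adjusted p for 14. CHD1, the 10 PHO genes among the largest falls, BNA4 and BAT2 were past the threshold in every alternative that gave an adjusted p; DESeq2 gave none for PHO89. Of 22 further genes named after their values were seen, 17 kept their call with DESeq2 (1 got no adjusted p), 18 with total gene counts, 21 with the stricter filter, 16 to 21 when 1 library was left out and 22 otherwise; PHO86 lost its call with DESeq2, with total gene counts and without either deletion replicate.

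The 260 changed genes (92 higher, 168 lower) became 486 (184 and 302) at an adjusted p under 0.1, which is a looser threshold. DESeq2 called 153, 33 of them higher, and 152 of the 153 were among the 260; it gave no adjusted p for 2660 genes. Total gene counts called 176 higher and 65 lower, a shift of the scale, with 157 calls shared. Leaving out 1 library gave 133 to 577 changed genes, 58 to 213 higher and 70 to 364 lower; the cause was not tested. The replicate number as a block gave 424 changed genes, 165 higher and 259 lower, including all 260. Same-numbered libraries did not deviate together (correlation of deviations from the group means across genes 0.014), so the numbers are not taken to pair the libraries. The block changed the number of introns lower relative to their genes from 1 to 0. Pseudocounts and filters planned for normalized values were not run, because counts were analysed.

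The 8 introns lower in the deletion numbered 1 with DESeq2 and 2 with the stricter filter, which tested 23 introns. TMM factors from the introns remove a change common to all introns and gave 4, of which 2 were shared. Leaving out 1 library gave 0 to 4. Relative to the gene, the 1 intron became 0 with DESeq2, 0 with the stricter filter, 0 with limma-voom and 2 with exon counts of the host. Leaving out 1 library gave 0 to 6. The log2 ratio of intronic shares, -0.44, was -0.17 as the difference of library medians over introns (-0.0391 in ribosomal protein genes and 0.0346 in other genes). It was -0.59 without ribosomal protein genes and -0.16 without snoRNA introns. It was -0.0991 without IMD4 alone, intron and gene, which together hold much of the fall. With all introns it stayed between -0.53 and -0.34 when 1 library was left out. The 8 gene lists called by camera became 0 with an estimated correlation and 3 with fry, which compares no list with other genes. Estimated correlations were -0.03 for the PHO list, -0.02 for amino acid biosynthesis, -0.03 for glycolysis, -0.02 for G1/S genes and 0.0001 for chaperones. These lie below the preset of 0.01, so a higher correlation cannot be why these lists were lost. For the PHO list the camera p went from 3.21e-13 to 0.0153 although the estimated correlation was the lower one. Failing the estimated form is therefore no evidence that the genes of these lists are correlated. They were 0.20 for ribosomal protein genes, 0.26 for the stress list and 0.04 for ergosterol synthesis. The difference of medians between introns of ribosomal protein genes and others, -0.16, did not pass, and lay between -0.38 and -0.14 when 1 library was left out, passing without deletion replicate 1. Relative to the gene it was -0.20, lost with an estimated correlation (-0.20, p = 0.132), and lay between -0.30 and -0.17 when 1 library was left out. The cause of these differences was not tested.

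Some values that did not pass the test changed sign. RPL30 was at 0.0685 and RPS9A at 0.0889 with total gene counts, and RPS9A was at 0.00418 with the stricter filter. When 1 library was left out, RPL30 lay between -0.14 and 0.0798 and RPS9A between -0.0871 and 0.0670. With total gene counts the medians of the ribosome biogenesis, elongation, sulfur and daughter-cell lists were 0.0785, 0.0691, 0.10 and 0.0489, and with the replicate block that of the sulfur list was 0.0112. Total gene counts moved the median of all genes to 0.11, and minus that median the 4 lists stayed below 0 (-0.03, -0.04, -0.006 and -0.06), so with that scaling the signs changed by a shift common to all genes. The cause of the other changes of sign was not tested. When 1 library was left out these medians lay between -0.0952 and 0.0455 for ribosome biogenesis, between -0.0680 and 0.00864 for elongation factors and between -0.12 and 0.13 for sulfur genes. Over all genes named by the rule and all alternatives, 930 results kept their direction and side of the threshold, 78 fell out of it, 23 came past it and 6 changed sign. Depth limits the intron tests: the introns held 5985 to 10368 reads per library against 2145684 to 4117998 over genes.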

Other observations

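The test of genes near chromosome ends was planned as a hypothesis before its result was seen, as were those on gene length, GC content, chromosomes, adjacent genes and intron-containing genes; leaving PHO genes out of the chromosome-end list was chosen only after its result was seen.

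Genes that changed in the same direction included neighbours. BAT2 lies next to YJR149W on chromosome X (705744 to 708374), and both rose, by 1.58 and 1.24 on the log2 scale. HXT4 and HXT1 are neighbours on chromosome VIII (287081 to 292625), as are HXT7 and HXT6 on chromosome IV, and the glycine cleavage gene GCV3 rose (0.74) next to YAL044W-A (0.56) on chromosome I. MUM3 (-0.66) and MBF1 (-0.72) fell side by side on chromosome XV, as did YML131W (-0.68) and ERO1 (-0.52), which encodes a thiol oxidase of the endoplasmic reticulum, on chromosome XIII. A candidate explanation for the 11 adjacent pairs called in the same direction is that they cluster, but 643 of 10000 random placements of the calls gave as many (permutation p = 0.0643, random median 6, 95% of placements from 2 to 12). Clustering therefore cannot be told apart from chance at this number of pairs (11), and HXT7 and HXT6 also share reads.

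Of 217 tested genes within 25 kb of a chromosome end, 13 fell and 4 rose, the median log2 fold change was -0.08, and camera gave p = 0.0148 (p = 0.0506 with an estimated correlation). Without the PHO genes, 9 of 212 fell and 4 rose and camera gave p = 0.0524 (p = 0.0777 with an estimated correlation), at a median of -0.07, so the size changed little.

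Intron-containing genes outside the ribosomal protein genes may have been affected as a class if splicing mattered for their levels, but camera gave p = 0.907 over 155 genes (p = 0.928 with an estimated correlation). Of these, 2 rose and 5 fell, at a median of 0.02. Intron-containing ribosomal protein genes, 101 in number, had 9 lower and 0 higher members and a median of -0.12 (camera p = 1.60e-06; p = 0.275 with an estimated correlation), next to -0.13 for all ribosomal protein genes.

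Technical trends across genes were small. Spearman correlations of the log2 fold change across 5486 genes, which are not independent replicates, were -0.154 with gene length and -0.0481 with GC content. The value for GC lies within the range set in advance as excluding a bias. That for length, -0.154, lies between the ranges set for a bias and for none, so a weak length bias cannot be told apart from a property of the genes. A gained or lost chromosome is unlikely, as the chromosome median farthest from 0 was 0.0469, on chromosome I, and the 16 medians ran from -0.02 to 0.05.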
